A study of Bos taurus with 6 samples.

How the data were processed

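The series holds RNA sequencing of 6 cell lines grown from ear tissue of cloned cattle that had survived to 1 month of age. Per the labels, 3 lines came from clones made with fetal oviduct epithelial cells as nuclear donors and 3 from clones made with fetal fibroblasts. Pieces of epidermal tissue were minced and cultured in medium with serum, RNA was extracted with TRIzol, and sheared cDNA was sequenced on an Illumina HiSeq system, per the labels' protocols. The labels do not say whether the lines of a donor type come from separate animals or share a nuclear donor, so no p-value reaches beyond these lines. The p-values of single genes and isoforms measure only the spread between these lines.

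For each line the authors deposited 1 gene table and 1 isoform table. Per the file headers, each table gives an expected count, the TPM, the FPKM, a length and an effective length, and the isoform tables add the percent of a gene's expression that each isoform carries. The expected counts are the authors' estimates of fragments per gene or isoform, are not scaled for depth and need not be whole. The deposited TPM values are scaled within a sample, and the deposited FPKM values are scaled by effective length and depth. HISAT2, Bowtie2 and the genome build bosTau9 are named in the submitters' processing notes, with no role or version. The quantifier, the annotation release and the strand setting are not given in the sources used here, so a gene and an overlapping antisense gene, or near-identical copies, can share fragments. The gene tables list 27672 loci, of which 1466 carry a number in place of a GeneID and took between 4.22% and 5.96% of the counts of a library. Of the 26206 GeneIDs, 23531 (89.8%) matched a symbol in a RefSeq gene table of the assembly ARS-UCD2.0, which was used for names only, and 2675 did not. Gene length in these tables is weighted by the isoforms of each library, so the ratio of FPKM values and the fold change of counts can differ for a gene, and they had opposite signs for 27 of the genes past the threshold.

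Total expected counts per library were between 18358728 and 20486975. Fragment length was read as length minus effective length in transcripts longer than 2000 bases. A count of 0 was given an upper limit of 3 counts per library, and this limit covers counting error only. Pairs of libraries were compared by a chi-square statistic over genes with at least 20 counts, and no pair agreed within sampling noise.

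Expected counts were rounded to whole numbers. Genes were filtered with edgeR's filterByExpr, scaled by TMM and tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 fold change is the oviduct-donor minus the fibroblast-donor lines, with its standard error (SE) taken from the F statistic. Isoforms were tested in the same way. Before the data were examined, 42 gene lists were written that cover the epigenetic machinery, cell types of skin and of the donors, and states of cultured cells. The 39 lists with at least 3 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2. The correlation between genes was preset to 0.01. Camera compares the genes of a list with the other tested genes, so its p-values do not measure the spread between lines alone. Beside each list stand the members past the threshold over all genes tested and those adjusted over the list alone. Camera with a correlation estimated per list, and fry, which tests whether the genes of a list move on balance in 1 direction, were run as alternatives. KEGG pathways named in the deposited tables, of 10 to 300 tested genes, were tested with camera after the other results had been seen. The similarity of libraries was tested with an exact one-sided permutation test over the 10 splits of the 6 libraries, whose smallest p is 0.1.

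The rule for named genes was also fixed before the data were examined. It takes genes with a symbol that are the 10 largest rises and 10 largest falls past the threshold with groups that do not overlap and a mean FPKM of at least 1 in the higher group. It adds up to 4 members of each list with the smallest p past the threshold (or 1 where none passed), XIST and Y-linked genes, and the 3 most expressed genes past the threshold in each direction. The text gives a part of these genes, and says where a gene was chosen after its values were seen.

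The scripts were tested on simulated counts with 100 loci changed 2-fold and 100 changed 4-fold, drawn from the means of the real libraries. For genes (13887 run), edgeR recovered 52% of 100 genes changed 2-fold and 86% of 100 changed 4-fold, with 5.48% false calls. DESeq2 (1.42.0) recovered 66% and 88%, with 23.4% false calls. For isoforms (32878 run), edgeR recovered 0% at 2-fold and 9% at 4-fold. Far fewer loci were changed here than passed in the real data, and the adjustment of p depends on that share. These percentages therefore do not carry over to the real comparison.

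Alternatives fixed beforehand were DESeq2, other size factors, other filters, a 2-fold threshold, limma on log2 FPKM with a pseudocount of 1 or 0.1, leaving out each library, and the replicate number as a block. Alternatives added after seeing the data were the removal of a trend with transcript length (a smooth curve with 6 degrees of freedom per library), effective length as an offset, a test without the numbered loci, and list counts without oviduct-donor replicate 1. Mitochondrially encoded genes, of which 0 matched by symbol, and skeletal muscle markers, of which 1 could be tested, were too few for a list test, as were XIST and RLIM, the 2 genes found of the list of X inactivation and Y-linked genes. Values of some single genes in the lists are not reported here, while the list counts and tests include them.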

Results

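Gene expression was measured by RNA sequencing in cell lines cultured from the ears of surviving cloned cattle. The clones had been made by nuclear transfer from fetal oviduct epithelial cells (3 lines) or from fetal fibroblasts (3 lines). The comparison asks whether cells of the same tissue, after reprogramming and differentiation, still differ by the cell type of the nuclear donor. Total expected counts were 20285881, 20486975 and 20353550 in oviduct-donor replicates 1 to 3 and 18984392, 19605269 and 18358728 in fibroblast-donor replicates 1 to 3. The libraries also differed in fragment length, which was 294, 287 and 281 bases in the oviduct-donor and 259, 259 and 262 bases in the fibroblast-donor libraries. This difference follows the donor types without overlap, so it and the donor type cannot be told apart. FPKM values below are means ± SD with n = 3 lines per donor type.

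Expression differed between the donor types for a large part of the transcriptome. Of 13887 genes tested with edgeR, 2513 were higher and 2610 lower in oviduct-donor lines at an adjusted p under 0.05, and 662 and 1005 of these differed at least 2-fold. As 36.9% of all tested genes passed, a list with a similar share of changed members is not set apart by its count. The groups did not overlap for 53.1% of the tested genes, where chance gives 10%. Log2 expression correlated at a mean r of 0.975 across genes between lines of the same donor type and 0.932 between donor types, and no split of the libraries gave a larger gap (exact permutation p = 0.1, the smallest that 3 against 3 allows). The count depended on single libraries: without fibroblast-donor replicate 3 it was 2789, and without oviduct-donor replicate 3 the genes higher in oviduct-donor lines numbered 1658. With limma on log2(FPKM + 1) the calls were 1859 higher and 3445 lower, on a scale where the median of all genes shifted by -0.10.

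Among the largest rises in oviduct-donor lines was MMP9, a gelatinase that degrades basement membrane collagen, at 4.25 ± 2.08 FPKM against 0.120 ± 0.0458 (log2 fold change 5.27, SE 0.53, edgeR adjusted p = 0.00127). LAMC3, a laminin chain, stood at 4.34 ± 0.721 against 0.213 ± 0.162 FPKM, and OLFM2 at 3.25 ± 1.02 against 0.123 ± 0.108. ADNCR, a non-coding RNA, had 31.8 ± 4.15 against 2.71 ± 1.97 FPKM. Among the largest falls were PET117, a factor for assembly of cytochrome oxidase (0.583 ± 0.357 against 22.2 ± 0.667 FPKM, log2 fold change -5.19), and DKK2, a secreted Wnt antagonist (0.437 ± 0.131 against 5.55 ± 2.44 FPKM, log2 fold change -3.52). BRCA2 and POLQ, which act in repair of DNA breaks, fell by 3.62 and 3.41 on the log2 scale. TREX2 was listed at 0 in each fibroblast-donor library and was at least 11.3-fold higher in oviduct-donor lines against the limit of 3 counts per library. PNISR (at least 44.6-fold higher) and ZNF449 (at least 19-fold lower) were also at 0 in 1 donor type. For both, a further locus with the same protein name was counted in all 6 libraries, so their values are uncertain. The further PNISR locus had 4.90 ± 1.23 against 14.2 ± 0.945 FPKM, lower in oviduct-donor lines, so a rise of PNISR as a whole is not shown. That of ZNF449 had 2.59 ± 0.0458 against 3.01 ± 0.358 FPKM.

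Cell cycle genes fell together in oviduct-donor lines. Of 40 tested members, 37 were lower and 0 higher (39 and 0 adjusted over the list alone), with a median log2 fold change of -1.71 (camera adjusted p = 3.89e-13, and adjusted p = 0.841 with an estimated correlation). The centromere-associated motor CENPE stood at 0.390 ± 0.164 FPKM against 9.05 ± 0.845, a log2 fold change of -4.37 (SE 0.29, edgeR adjusted p = 0.000903). The S-phase cyclin CCNE2 fell by 2.20, the helicase subunit MCM6 by 1.01 and HMMR, a spindle-associated protein, by 2.48 on the log2 scale. Without oviduct-donor replicate 1, 39 of the 40 members were lower.

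Among p53 and senescence genes, 9 of 30 were higher and 3 lower (9 and 3 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.527). CDKN2A, which encodes inhibitors of cell cycle entry, stood at 352 ± 20.9 FPKM against 136 ± 24.9 (log2 fold change 1.46, SE 0.15, edgeR adjusted p = 0.00131). CDKN1A, the p21 inhibitor, rose by 0.87 on the log2 scale (150 ± 10.9 against 90.0 ± 10.9 FPKM). The nuclear lamina gene LMNB1 fell by 2.02 (10.9 ± 4.29 against 48.7 ± 5.57 FPKM), and IGFBP7 rose by 2.57. Without fibroblast-donor replicate 3, 5 members were higher.

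**Figure D1:**
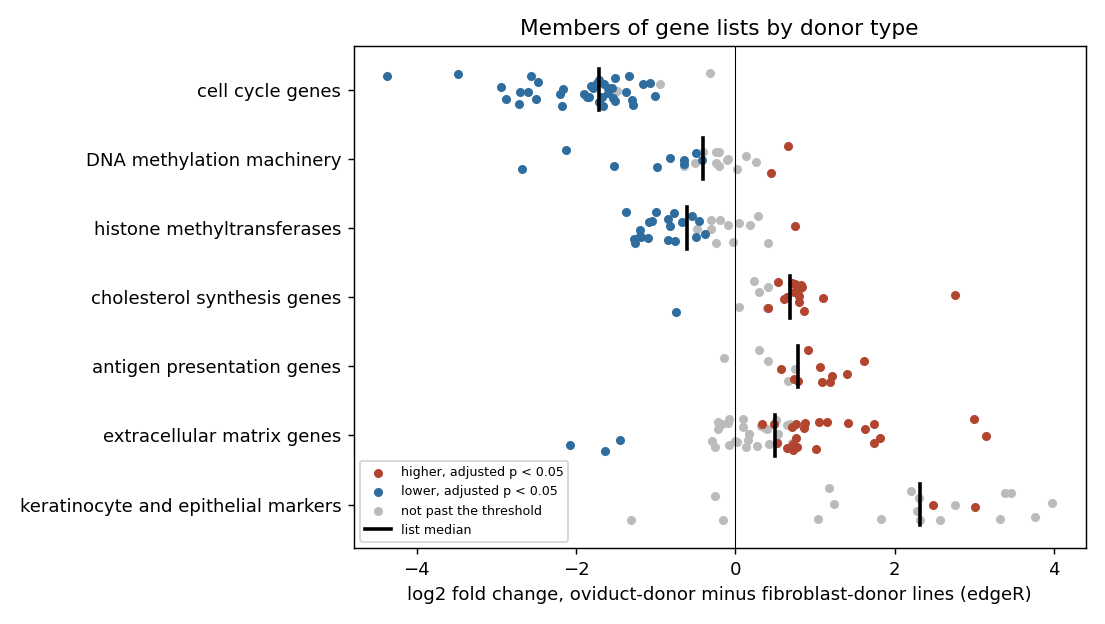
Log2 fold change (edgeR, oviduct-donor minus fibroblast-donor lines) of the tested members of 7 gene lists, 1 point per gene, coloured by direction where the adjusted p is under 0.05, with the list median as a bar. The medians lie at -1.71 for cell cycle genes, -0.41 for DNA methylation machinery and -0.61 for histone methyltransferases, and at 0.68, 0.79, 0.50 and 2.31 for the other lists from cholesterol synthesis to keratinocyte and epithelial markers, the last with 2 of 20 members past the threshold.

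Genes of DNA methylation were lower in part. Of 23 tested members, 9 were lower and 2 higher (10 and 2 adjusted over the list alone), with a median log2 fold change of -0.41 (camera adjusted p = 0.0203, and adjusted p = 0.643 with an estimated correlation). DNMT1, the maintenance methyltransferase, stood at 10.1 ± 2.13 FPKM against 22.3 ± 0.891 (log2 fold change -0.99, SE 0.15, edgeR adjusted p = 0.00377). UHRF1, which recruits DNMT1 to newly replicated DNA, had 3.69 ± 1.90 against 25.9 ± 4.49 FPKM, and the chromatin remodeller HELLS had 3.41 ± 0.917 against 15.9 ± 1.51. ZFP57, which protects methylation at imprinted regions, fell by 0.64. With the trend of fold change with transcript length removed, 7 members were lower and 4 higher, and the list did not pass camera (adjusted p = 0.109). Its median moved toward 0, to -0.29 (quartiles -0.42 and 0.01, against -0.64 and -0.10 before). On log2(FPKM + 1), with 21 members tested, the list did not pass either (adjusted p = 0.056, median -0.39).

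Histone methyltransferase genes were lower for 20 of 32 members and higher for 1 (20 and 1 adjusted over the list alone), with a median log2 fold change of -0.61 (camera adjusted p = 9.1e-05, and adjusted p = 0.264 with an estimated correlation). The Polycomb subunit SUZ12 stood at 4.81 ± 0.426 FPKM against 13.1 ± 1.11 (log2 fold change -1.37, SE 0.12, edgeR adjusted p = 0.00107), and KMT2E and NSD1 fell by 1.09 and 1.05. KMT2D fell by 1.20, and with the length trend removed its log2 fold change was -0.22 with an adjusted p of 0.231. With that trend removed 15 members of the list were lower (camera adjusted p = 0.0445). Histone acetyltransferase genes were lower for 8 of 18 and higher for 2 (8 and 3 adjusted over the list alone, camera adjusted p = 0.362). HAT1, which acetylates new histone H4, stood at 17.3 ± 2.08 against 40.7 ± 1.55 FPKM, and ING4 rose by 0.62. With the length trend removed 2 acetyltransferase genes were lower. Without oviduct-donor replicate 3 or fibroblast-donor replicate 1 there were 5, and without fibroblast-donor replicate 3 there were 4. The acetyltransferase list passed fry (adjusted p = 0.0312). Deacetylases and sirtuins moved both ways, with 7 of 22 higher and 6 lower (7 and 6 adjusted over the list alone, camera adjusted p = 0.884): HDAC5 and SIRT2 rose by 0.77 and 0.79. Without oviduct-donor replicate 2 the test called 1 lower, without oviduct-donor replicate 3 it called 3 higher and 1 lower, and without fibroblast-donor replicate 3 it called 2 higher and 0 lower (edgeR). Among 21 histone demethylases, 4 were lower and 2 higher (4 and 2 adjusted over the list alone, camera adjusted p = 0.527), with log2 fold changes of -1.35 for KDM5A and 0.76 for KDM5B. Genes of m6A RNA methylation were lower for 10 of 20 and higher for 2 (10 and 3 adjusted over the list alone, camera adjusted p = 0.0744), among them RBM15, a subunit of the writer complex, at 0.780 ± 0.125 against 4.47 ± 0.640 FPKM. This list passed camera without fibroblast-donor replicate 2 (adjusted p = 0.0422), on log2(FPKM + 1) (0.0167) and with no filter (0.0464), and it passed fry (0.0033). With an estimated correlation it did not pass (camera adjusted p = 0.841).

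Across all tested genes the fold change went with transcript length. The median log2 fold change was 0.15 in the shortest 10% of genes and -0.37 in the longest 10% (Spearman rho -0.221 across genes, which are not independent replicates). In the longest 10%, 37.2% of genes were lower and 4.75% higher in oviduct-donor lines, and in the shortest 10% 13.4% were lower and 24.3% higher.

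**Figure D2:**
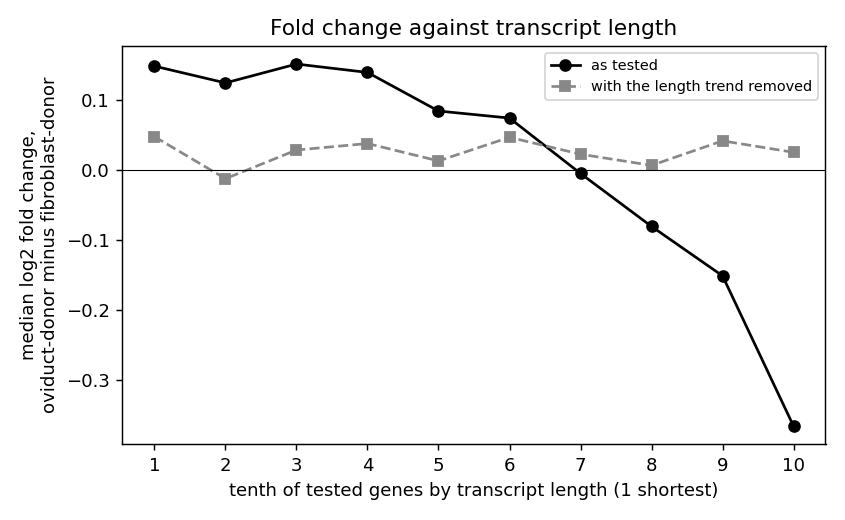
Median log2 fold change (oviduct-donor minus fibroblast-donor lines) of tested genes in 10 equal groups by transcript length, from the shortest (1) to the longest (10), as tested (circles) and with the length trend removed (squares). The median as tested lies at 0.15 in the shortest group and at -0.37 in the longest.

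Of 31 imprinted genes tested, 6 were higher and 5 lower (6 and 5 adjusted over the list alone, camera adjusted p = 0.625). IGF2, a paternally expressed growth factor, stood at 2.93 ± 0.555 FPKM against 0.340 ± 0.131 (log2 fold change 3.26, SE 0.34, edgeR adjusted p = 0.00131). CD81, BLCAP and GNAS rose by 1.49, 0.94 and 0.48. Leaving out single libraries gave 5 to 9 higher and 3 to 7 lower imprinted genes. XIST, the RNA that coats the inactive X chromosome, was counted in all 6 libraries, at 6.53 ± 2.75 FPKM in oviduct-donor and 19.7 ± 1.05 in fibroblast-donor lines (log2 fold change -2.13, SE 0.34, edgeR adjusted p = 0.00459). RLIM, an X-linked activator of XIST, fell by 0.91. No Y-linked gene of the list matched a symbol, so these were not analysed here.

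**Figure D3:**
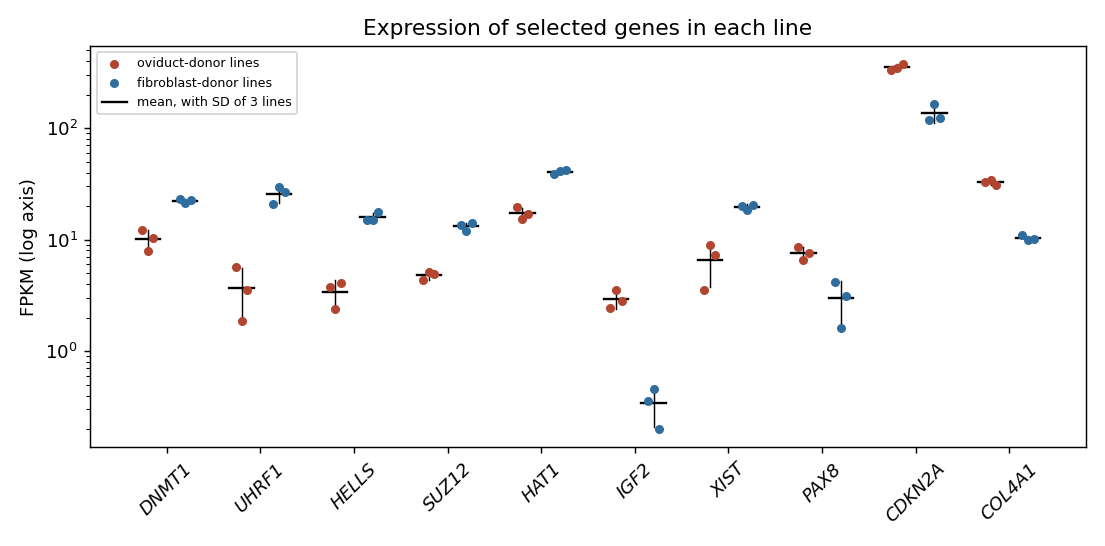
FPKM (log axis) of 10 genes in each of the 3 oviduct-donor and 3 fibroblast-donor lines, with the mean and SD of each donor type. The 3 values of 1 donor type lie apart from the 3 of the other for each gene shown, with DNMT1 at 10.1 ± 2.13 against 22.3 ± 0.891 FPKM.

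Cholesterol synthesis genes were higher in oviduct-donor lines for 15 of 22 members and lower for 1 (18 and 1 adjusted over the list alone), with a median log2 fold change of 0.68 (camera adjusted p = 5.22e-05, and adjusted p = 0.841 with an estimated correlation). DHCR7, which makes cholesterol from its direct precursor, stood at 86.7 ± 7.70 FPKM against 44.1 ± 5.71 (log2 fold change 1.10, SE 0.12, edgeR adjusted p = 0.0014), and IDI1 and FDPS rose by 0.83 and 0.71. Antigen presentation genes were higher for 10 of 15 and lower for 0 (12 and 0 adjusted over the list alone, median log2 fold change 0.79, camera adjusted p = 0.000777, and adjusted p = 0.841 with an estimated correlation). TAPBP, which loads peptides onto class I molecules, had 82.4 ± 8.64 against 34.5 ± 3.55 FPKM, the immunoproteasome subunits PSMB8 and PSMB10 rose by 1.08 and 1.21, and BOLA-NC1, a class I gene with close relatives and so uncertain, rose by 1.62. Without fibroblast-donor replicate 3, 6 members were higher. Inflammatory mediators were higher for 8 of 29 and lower for 1 (5 and 1 adjusted over the list alone, median 0.72, camera adjusted p = 0.035, and adjusted p = 0.841 with an estimated correlation), among them CXCL16 (92.0 ± 17.1 against 50.4 ± 8.47 FPKM) and IL11, which rose by 1.35. This list did not pass camera without oviduct-donor replicate 1 (adjusted p = 0.0506), without oviduct-donor replicate 2 (0.0549) or without fibroblast-donor replicate 2 (0.0835), nor did it pass fry (0.0955). With the length trend removed it did not pass camera (adjusted p = 0.0697), with a median of 0.60 (quartiles 0.17 and 1.06, against 0.29 and 0.99 before). Its higher members numbered 5 without oviduct-donor replicate 2, 5, 4 and 2 without oviduct-donor replicate 3, fibroblast-donor replicate 2 and fibroblast-donor replicate 3, and 13 without fibroblast-donor replicate 1.

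Extracellular matrix genes were higher for 22 of 52 members and lower for 3 (22 and 3 adjusted over the list alone), with a median log2 fold change of 0.50 (camera adjusted p = 0.000849, and adjusted p = 0.841 with an estimated correlation). The basement membrane collagens COL4A1 (32.8 ± 1.75 against 10.4 ± 0.485 FPKM, log2 fold change 1.82, SE 0.09, edgeR adjusted p = 0.000767) and COL4A2 rose, and COL18A1 and COL5A3 rose by 3.15 and 2.99. Matrix proteases and inhibitors were higher for 10 of 26 and lower for 2 (11 and 2 adjusted over the list alone, camera adjusted p = 0.0527), with PLAT and PLAU, both activators of plasminogen, up by 1.09 and 0.79. The proteases passed camera without oviduct-donor replicate 3 (adjusted p = 0.0336), fibroblast-donor replicate 1 (0.0142) or fibroblast-donor replicate 3 (0.0433), with 6 members higher in the first of these fits and 5 in the last. They also passed on log2(FPKM + 1) (0.0176), with no filter (0.0142), with the length trend removed (0.0492) and by fry (0.009). With an estimated correlation they did not (camera adjusted p = 0.841). Without fibroblast-donor replicate 2, 6 were higher. Fibroblast markers were higher for 6 of 21 and lower for 1 (6 and 0 adjusted over the list alone, camera adjusted p = 0.0792): VIM stood at 9972 ± 1074 against 6774 ± 374 FPKM, and PDGFRB rose by 1.17. Without oviduct-donor replicate 1, 9 fibroblast markers were higher and the list passed camera (adjusted p = 0.0077), as it did without fibroblast-donor replicate 1 (0.0142) and with no filter (0.0351). With an estimated correlation its camera adjusted p was 0.841.

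Epithelial markers were highest in a single line. Of 20 keratinocyte and epithelial markers tested, 2 were higher and 0 lower (0 and 0 adjusted over the list alone, median log2 fold change 2.31, camera adjusted p = 0.089). Oviduct-donor replicate 1 held the highest value of 18 of the 20, with a median of 32.7 FPKM. The other oviduct-donor lines had medians of 7.36 and 4.38 FPKM, and the fibroblast-donor lines 3.98, 3.84 and 0.295. The laminin chain LAMB3 and the integrin ITGB4 passed the threshold (adjusted p = 0.043 and 0.0484) and did not without oviduct-donor replicate 1 (adjusted p = 0.117 and 0.121). They also lost their calls without oviduct-donor replicate 2 or any of the fibroblast-donor libraries (adjusted p from 0.0623 to 0.143). The list passed camera without oviduct-donor replicate 3 (adjusted p = 0.00452), fibroblast-donor replicate 1 (0.0142) or fibroblast-donor replicate 2 (0.0227). It also passed with the replicate number as a block (0.000642, with 8 members higher), on log2(FPKM + 1) (0.0273) and with no filter (0.0059). It did not pass with an estimated correlation (camera adjusted p = 0.841) or without oviduct-donor replicate 1 (0.529). The basal keratin KRT14, chosen after its values were seen, had 158 FPKM in that line and 20.9, 8.87, 7.45, 7.25 and 0.25 in the others. Of 8 oviduct and Mullerian duct genes tested, 3 were higher and 1 lower (3 and 1 adjusted over the list alone, camera adjusted p = 0.58). PAX8, a transcription factor of the Mullerian duct, stood at 7.57 ± 1.02 against 2.97 ± 1.28 FPKM (log2 fold change 1.50, SE 0.32, edgeR adjusted p = 0.0108), and MSX1 fell by 0.70. The other higher genes were CCDC78 and MUC16, the latter at 0.0900 ± 0.0458 against 0.0200 ± 0.0173 FPKM. Both lost their calls without oviduct-donor replicate 2 (adjusted p = 0.0507 and 0.1), which left PAX8 alone of the 3. MUC16 lost its call in 5 of the 6 fits that leave out a library (0.067 to 0.104). Smooth muscle and myofibroblast markers were higher for 4 of 14 and lower for 1 (5 and 2 adjusted over the list alone, camera adjusted p = 0.208), with MYL9 and LMOD1 up by 1.06 and 1.02. Without oviduct-donor replicate 1, the line with the high epithelial markers, 2 of the 14 were higher and 0 lower (edgeR). Without oviduct-donor replicate 3 or fibroblast-donor replicate 1, 2 were higher as well. Adipocyte markers were higher for 2 of 6 (2 adjusted over the list alone, camera adjusted p = 0.685, fry adjusted p = 0.0312), endothelial markers for 1 of 4 (1 adjusted over the list alone, 0.884), and cartilage markers were lower for 1 of 8 (0 adjusted over the list alone, 0.541). The adipocyte genes, CIDEA and PLIN1, both lost their calls without fibroblast-donor replicate 2 (adjusted p = 0.0535 and 0.0512) or 3 (0.0763 and 0.0747), and PLIN1 lost its call in 5 of the 6 fits that leave out a library. The endothelial gene VWF lost its call without fibroblast-donor replicate 3 (0.0589), and the cartilage gene SOX5 in 5 of the 6 fits (0.0548 to 0.133). With edgeR, 0 of 4 melanocyte, 0 of 5 immune cell, 0 of 6 bone, 0 of 4 Schwann and neural and 0 of 4 pluripotency genes passed the threshold. Their camera adjusted p-values were 0.622, 0.986, 0.995, 0.545 and 0.911. The smallest unadjusted p-values were 0.0432 for PMEL among melanocyte, 0.327 for CORO1A among immune cell, 0.0583 for NCAM1 among Schwann and neural and 0.0217 for TFAP2C among pluripotency genes. Of the bone markers, 0 of 6 had an unadjusted edgeR p under 0.05.

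Genes of body position moved both ways. Of 38 positional transcription factors, 6 were higher and 3 lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.527). The higher members numbered 2 or 3 without any 1 of the oviduct-donor libraries or fibroblast-donor replicate 3. FOXF1 stood at 12.2 ± 0.933 against 3.34 ± 1.58 FPKM and IRX5 rose by 0.98. Of 12 HOX genes, 2 were lower and 0 higher (0 and 0 adjusted over the list alone, camera adjusted p = 0.58). These 2, HOXB6 and HOXC4, had mean FPKM of at most 1.33, and neither call held throughout when single libraries were left out. HOXB6 lost its call without oviduct-donor replicate 3 or fibroblast-donor replicates 1 or 2 (adjusted p from 0.0521 to 0.0803). HOXC4 lost its call in 5 of the 6 fits (0.0547 to 0.107).

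Signalling lists did not pass camera and held changed members in both directions. Their counts are to be read beside the 36.9% of all tested genes that passed the threshold. Among 35 TGF-beta and BMP genes 9 were higher and 4 lower (9 and 4 adjusted over the list alone, adjusted p = 0.527): TGFB1 stood at 96.0 ± 8.61 against 42.5 ± 5.48 FPKM, and ID1, a target of BMP signalling, at 8.23 ± 1.04 against 31.8 ± 8.34. Among 36 Wnt genes 5 were higher and 2 lower (5 and 2 adjusted over the list alone, adjusted p = 0.316), with log2 fold changes of 1.49 for DKK3 and -1.78 for APC, a negative regulator of the pathway. Among 29 FGF and IGF genes 6 were higher and 4 lower (6 and 4 adjusted over the list alone, adjusted p = 0.541), and FGF7 stood at 50.7 ± 6.38 against 117 ± 18.0 FPKM. Of 28 interferon response genes 4 were higher and 1 lower (1 and 1 adjusted over the list alone, adjusted p = 0.527), with CMPK2 up by 1.56. STAT2 and IRF7 lost their calls without oviduct-donor replicate 3 (adjusted p = 0.0736 and 0.0601) or fibroblast-donor replicate 2 (0.0726 and 0.0773). STAT2 also lost its call without oviduct-donor replicates 1 and 2 (0.0668 and 0.0866) and IRF7 without fibroblast-donor replicates 1 and 3 (0.079 and 0.151), so each lost it in 4 of the 6 fits. The higher interferon genes numbered 1 without oviduct-donor replicate 3 or fibroblast-donor replicate 2, and 2 without oviduct-donor replicate 2 or fibroblast-donor replicate 3. Apoptosis genes were higher for 6 of 27 and lower for 5 (7 and 5 adjusted over the list alone, adjusted p = 0.541), and BCL2, which opposes cell death, stood at 1.59 ± 0.656 against 7.32 ± 1.99 FPKM. Immediate early genes were higher for 4 of 22 and lower for 2 (4 and 2 adjusted over the list alone, adjusted p = 0.491): EGR1 rose by 1.18 and FOSL1 fell by 1.93. Without oviduct-donor replicate 3 the higher FGF and IGF and the higher apoptosis genes numbered 3 each and the higher Wnt genes 8, without fibroblast-donor replicate 1 the higher Wnt genes 9, and without fibroblast-donor replicate 3 the higher apoptosis genes 1. Without oviduct-donor replicate 1, 5 immediate early genes were lower and 4 higher. Over the 6 fits that leave out a library, the lower members ranged from 2 to 5 for TGF-beta and BMP, 2 to 5 for Wnt and 1 to 4 for apoptosis genes, and the higher immediate early genes from 2 to 6. The Wnt list passed fry (adjusted p = 0.00198).

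Metabolic and stress lists were also mixed. Glycolysis genes were higher for 4 of 23 and lower for 4 (4 and 3 adjusted over the list alone, adjusted p = 0.986), hypoxia response genes for 5 and 4 of 25 (5 and 4 adjusted over the list alone, 0.986), and nuclear oxidative phosphorylation genes for 7 and 5 of 45 (5 and 5 adjusted over the list alone, 0.986). HIF1A, the oxygen-sensing transcription factor, stood at 22.9 ± 2.89 against 48.3 ± 9.20 FPKM. Fatty acid and lipid genes were higher for 5 of 24 and lower for 2 (9 and 2 adjusted over the list alone, adjusted p = 0.447), with FABP3 up by 1.27. Unfolded protein response and heat shock genes were higher for 6 of 29 and lower for 8 (6 and 8 adjusted over the list alone, adjusted p = 0.911): ATF4 rose by 0.66 and HSP90AA1 fell by 0.76. Without fibroblast-donor replicate 3 edgeR called 0 hypoxia genes higher and 1 lower, and the higher members numbered 2 for unfolded protein response and heat shock and 2 for oxidative phosphorylation genes. Of the latter 11 were lower without oviduct-donor replicate 1. Over the 6 fits that leave out a library, 1 to 3 glycolysis genes were higher and 2 to 6 lower, 0 to 6 hypoxia genes were higher and 1 to 6 lower, and 3 to 7 fatty acid and lipid genes were higher (edgeR). The most expressed genes past the threshold were TMSB4X, S100A4 and RPL31 among those higher and RPS29, RPL38 and RPS21 among those lower. With effective length as an offset, RPL38 and RPS21 had log2 fold changes of 0.11 and 0.04 in place of -0.41 and -0.35. S100A4, RPL31 and RPS21 lost their calls without fibroblast-donor replicate 3 (adjusted p = 0.0558, 0.0858 and 0.0623). RPL31 and RPS21 also did without oviduct-donor replicate 3 (0.058 and 0.0581), and RPL31 without fibroblast-donor replicate 1 (0.0575).

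Isoforms were tested separately. Of 32878 isoforms, 3105 were higher and 3548 lower in oviduct-donor lines (edgeR adjusted p under 0.05), in 4889 genes, of which 3319 also passed at the gene level. In 710 genes isoforms moved in both directions, and 413 of these genes did not pass at the gene level. Isoform counts and percentages are the authors' estimates, whose uncertainty was not modelled. Effective length as an offset was not run for isoforms, though fragment length differed between the donor types. The isoforms with the smallest p, chosen after their values were seen, were 1 of PRRX1, a mesenchymal transcription factor, which carried 53.9 ± 2.92% of the gene's expression in oviduct-donor and 1.90 ± 0.140% in fibroblast-donor lines, and 1 of NDRG1 (27.4 ± 5.53% against 2.06 ± 0.0757%). Leaving out a library gave 2497 isoforms without fibroblast-donor replicate 3, 3504 and 4011 without fibroblast-donor replicates 1 and 2, and 4155 without oviduct-donor replicate 3. With the replicate number as a block, edgeR called 0 isoforms (smallest adjusted p 0.0731, 8536 at an unadjusted p under 0.05). That fit has 2 residual degrees of freedom in place of 4. Of the isoforms called without the block, 100% kept their sign. As each replicate number occurs once in each donor type, the block hardly changes a fold change, so this was nearly fixed in advance.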

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

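The alternatives that remove the length trend, use effective length as an offset or leave out numbered loci were chosen after the data were seen. All counts here are edgeR calls unless another tool is named. Gene counts lay within 1.5 times of 5123 under DESeq2 (5532), other size factors (5123 and 5218, with 45.9% lower for upper-quartile factors), other filters (4816 and 5045), the length correction (4948) and the effective length offset (5343). The same replicate numbers did not pair lines: their deviations correlated at -0.08, -0.25 and 0.22. With the replicate block 3419 genes passed, 1614 of them higher, and 0 isoforms (0 higher, 0 lower), a fit with fewer residual degrees of freedom. At 2-fold or more 1667 genes (662 higher, 1005 lower) and 1843 higher isoforms were left. limma on log2(FPKM + 1) gave 1641 higher genes with no filter, and 5546 lower isoforms. Leaving out 1 library gave 2789 to 5036 genes (1189 to 2408 higher, 1600 to 2628 lower) and 2497 to 5722 isoforms (1327 to 2422 higher, 1170 to 3300 lower). Of the lists, 7 passed camera, 0 with an estimated correlation (2 at an unadjusted p), 11 by fry and 11 with no filter. The gap in correlation was 0.395 over the 500 most variable genes. Except where stated, the cause was not tested.

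Among single genes, NCOR1 went to 0.0452 with the length trend removed, and RPL38 and RPS21 to 0.107 and 0.0389 with effective length as an offset. Medians of lists that had not passed camera changed sign as follows. On log2(FPKM + 1) they were -0.0517 for deacetylases and sirtuins, -0.21 for oviduct genes, -0.0166 for p53 and senescence, -0.11 for glycolysis, -0.0305 for hypoxia and -0.00549 for TGF-beta genes. With no filter they were -0.0798 for pluripotency, -0.0721 for oviduct, -0.0899 for melanocyte, 0.16 for bone, -0.19 for adipocyte and -0.18 for hypoxia genes. Histone demethylases went to 0.0518 with the length trend removed. Leaving out libraries, the sign changed within these ranges: -0.0314 to 0.14 for deacetylases and sirtuins, -0.0688 to 0.21 for imprinted, -0.11 to 0.22 for pluripotency, -0.0362 to 0.14 for positional, -0.0833 to 0.48 for melanocyte, -0.15 to 0.38 for endothelial, -0.36 to 0.11 for immune, -0.20 to 0.0277 for bone, -0.18 to 0.55 for adipocyte, -0.0721 to 0.0995 for glycolysis, -0.11 to 0.11 for hypoxia, -0.0703 to 0.0219 for oxidative phosphorylation and -0.0616 to 0.0493 for heat shock genes.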

Other observations

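Pathways named in the deposited tables were tested after the other results had been seen. Of 238 KEGG pathways, camera called 9 higher and 13 lower in oviduct-donor lines with the preset correlation, and 0 with an estimated correlation (adjusted p of at least 0.716). Genes of lysosomes were higher for 52 of 117 and lower for 5 (camera adjusted p = 9.92e-05), those of glycosaminoglycan degradation for 10 and 0 of 16 (0.00181) and those of other glycan degradation for 11 and 0 of 17 (0.0252). Genes of DNA replication were lower for 30 of 35 and higher for 1 (8.83e-09), and those of the Fanconi anemia pathway for 27 and 1 of 51 (0.000316). Lower calls also prevailed among genes of ribosome biogenesis (31 lower and 4 higher of 77) and the spliceosome (47 lower and 4 higher of 136). Genes of the ribosome were higher for 73 and lower for 22 of 213 (0.039), and this call ended with the length trend removed (0.419).

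Genes chosen after their values were seen stood out in single lines or loci. In fibroblast-donor replicate 1, HOXD4 had 11.9 FPKM and HAND2 5.01, where the other 5 libraries had at most 0.94 and 0.27. Of 3 numbered loci annotated as the mitochondrial gene MT-ND5, 1 had 1.20 ± 0.461 FPKM in oviduct-donor and 463 ± 228 in fibroblast-donor lines (edgeR adjusted p = 0.000991, n = 3 lines each). The others had 1780 ± 276 against 969 ± 33.6 FPKM and 1350 ± 339 against 658 ± 541. They did not pass the threshold (log2 fold changes 0.03 and 1.2, edgeR adjusted p = 0.905 and 0.138). A fall of MT-ND5 as a whole is therefore not shown.

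The tests of the splits, of length against the cell cycle list and of loci with partners were chosen only after the result they bear on had been seen. Other splits of the 6 libraries into 3 and 3 gave 0 genes and 0 isoforms with edgeR, where the real split gave 5123 and 6653, the largest count in 1 of the 10 splits for each. The 10 splits are too few for a share under 0.05. Each other split mixes the donor types on both sides, so a difference between them adds to the spread within a side and lowers the counts. The counts of 0 therefore do not show what a comparison without any difference would give. For gene lists by camera, 6 of the 10 splits gave at least the 7 lists of the real split, and the highest of the other splits gave 13. By fry the real split gave 11 lists and each other split 0, with the same limit from mixed splits as for genes.

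The joint fall of cell cycle genes, DNMT1, UHRF1 and HELLS was weighed against technical explanations. With the length trend removed the median log2 fold change of the cell cycle list was -1.73 (95% bootstrap interval over genes -1.94 to -1.65). The median of the longest 10% of genes was only -0.37, so removing the trend could hardly bring a list at -1.71 near 0. That outcome was nearly fixed in advance. Without oviduct-donor replicate 1 the list median was -2.08 (-2.26 to -1.93), which argues against the keratinocyte markers of that line as the whole cause. This interval and those below resample genes, not lines, so they do not measure the spread between lines. Genes are not independent, with an estimated correlation of 0.893 in the cell cycle list. A hypothesis is that a lower share of dividing cells lowered the DNA methylation list through DNMT1, UHRF1 and HELLS alone. The other 20 members had a median of -0.23 with the length trend removed (-0.30 to 0.01). With more digits the interval ran from -0.2988 to 0.0096, so it just met the rule set beforehand for the hypothesis, to include 0 and lie above -0.3. However, 4 of the 20 were lower and 4 higher, so a median near 0 decides nothing. This condition on calls in both directions was not part of that rule. The donor cell type, the state of the cultures and the library difference in fragment length stay open and cannot be told apart in this design. As the labels do not say whether lines share a nuclear donor, a difference between the nuclear donors themselves stays open too.

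The lower level of long transcripts in oviduct-donor lines was weighed next. With effective length as an offset the median of the longest 10% of genes was -0.43 (-0.46 to -0.40). Transcripts in this group span at least 5877 bases, while mean fragment length differed by 27.4 bases between the donor types. Through effective length that difference could move the median only a little, so the outcome was nearly fixed in advance. It does not test other effects of fragment length. Leaving out the cell cycle list and the pathways called lower removed 55 of the 1389 genes in this group. The median of the other 1334 was -0.36 (-0.39 to -0.32), so the fall was present in the other long genes as well. So small a part could hardly move the median, so this could not test what those genes contribute. Whether the trend accounts for the lower histone methyltransferase genes stays open: their median went from -0.61 to -0.38 (-0.56 to -0.04) with it removed, and 15 members were lower in place of 20. RNA quality and library preparation were not tested, as no label gives them, and a biological cause stays open as well.

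At 10 loci each library of 1 donor type had at least 10 counts and each library of the other had 0, with 9 counted in oviduct-donor lines. Of the 8 with a protein name, 6 (75.0%) had another locus of the same name, against 12.0% of 12630 other named tested loci (Fisher exact test, one-sided p = 6.77e-05). Partners of PNISR and ZNF449 had been seen before the test, and without these loci 4 of 6 had one. A shared protein name does not show near-identical sequence. Some of these loci are numbered or have no symbol, so the kind of locus may also matter for this share. Reads split between near-identical loci may explain part of the loci at 0, which this test cannot settle. For the locus named OGDH without a symbol the values were 24.6 ± 6.16 against 0 FPKM, while OGDH itself had 17.0 ± 5.50 against 30.6 ± 6.18. The partner of PNISR also shifted the opposite way (4.90 ± 1.23 against 14.2 ± 0.945 FPKM). TMEM165 itself had 41.3 ± 1.87 against 57.4 ± 7.44 FPKM and NAP1L1 197 ± 5.51 against 285 ± 14.4. Their numbered loci at 0 in fibroblast-donor lines had 17.9 ± 3.70 and 11.8 ± 15.9 FPKM in oviduct-donor lines. Other loci named NAP1L1 had means of at most 1.58 FPKM and moved both ways. An opposite shift was not seen for B2M and ZNF449. The locus LOC783680, named B2M, had 10.5 ± 3.39 against 0 FPKM and B2M itself 1940 ± 554 against 1270 ± 114. ZNF449 had 0 against 2.08 ± 0.642 FPKM and its partner 2.59 ± 0.0458 against 3.01 ± 0.358. A sequence difference between nuclear donors was not tested, since reads were not used here.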
